A study of Mus musculus with 16 samples.

How the data were processed

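ATAC-seq libraries were made from Treg, preTreg, mSP and smSP cells sorted from the thymus of C57BL/6J mice, per the labels. Each of the 8 groups of population and genotype held 2 libraries, and the 4 libraries of a replicate came from 1 mouse. Reads were trimmed with Trimmomatic 0.36, aligned to mm10 with STAR 2.5.4b and handled with SAMtools 1.10, peaks were called with Genrich, whose version is not given in the sources used here, and DESeq2 1.24.0 was run in R 3.6.3, per the submitters' processing notes. The deposited values are a signal, namely reads per peak divided by a size factor for each library by the authors, for 73442 peaks called over the series. Whether reads were shifted for the transposase offset is not given in the sources used here. Peak numbers run to 84054, and 10612 numbers are absent, so peaks had been removed by an unstated filter. In all 16 columns 100% of the values were whole multiples of 1 read within 0.0001 reads, so whole reads were recovered, with size factors from 0.697 to 1.45 and 5585827 to 11437401 reads in peaks per library. A peak had a median of 38 to 76 reads per library, so small differences at weak peaks lie within counting error, and intervals and floors cover counting error only. Columns of unknown samples were absent from the table.

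Genes came from a RefSeq table of GRCm38.p6 without strand. The planned nearest transcription start could therefore not be placed, and a peak got the shortest gene body it overlapped or the nearest one within 50 kb, which gave a gene to 92.6% of peaks; 68.3% lie within a gene body. Exons and introns are not distinguished here. No genome sequence was used, so the planned motif test was not run.

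The main test was limma 3.58.1 (R 4.3.3, trend and robust) on log2(value + 1), for 73140 peaks with a mean of at least 10 over the 16 libraries, with 1 mean per group and Benjamini-Hochberg adjustment within each contrast at 0.05. Folds are on the log2(value + 1) scale, which understates changes of weak peaks. The genotype effect over all populations was tested on 1 mean per mouse, and its difference between populations by the F test of the 3 interaction terms. With 2 mice per genotype, the spread behind the p values over all populations comes only partly from the animals at that peak. The limma fit draws the spread of each peak toward that of peaks of similar signal. The other limma p values use 1 spread per peak shared by all 8 groups, not that of the compared groups alone. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, in 84 tests of 12 lists over 7 contrasts, adjusted within each contrast. The 12 lists, fixed before the data were examined, were Treg signature, TCR and co-stimulation response, IL-2 and STAT5 targets, NF-kB pathway, immature thymocyte, mature thymocyte and egress, CD4 lineage commitment, recirculating or effector Treg, innate-like T (NK and NKT included), B, myeloid and dendritic, and erythroid and stromal cells, of 153 genes in all, of which 137 had a peak. Some genes stand in more than 1 list. Peaks to be named were fixed by rule: all Foxp3 locus peaks, the 5 largest folds per direction among called peaks of each contrast, and 2 genes per list in the cell type contrasts. Other named genes, Cd24a, Rag1, Cd69 and Ccr7 in the mSP and smSP comparison and list members in the genotype comparisons among them, were chosen after their values were seen, as were the heat shock and immediate early lists. The result of 1 gene that had been examined is not reported here.

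The recovered reads were tested with edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 as alternatives. Scripts were tested on simulated data, in which 200 of 73140 peaks were changed. For genotype in Treg, limma recovered 16.4% of 1.5-fold, 50.4% of 2-fold and 93.6% of 4-fold changes, and for Treg against preTreg 35.1%, 82.4% and 99.2%. The share of false calls was 14.6% in Treg, 6.10% in preTreg, 25.1% in mSP and 15.4% in smSP for genotype, 12.9% for mSP against smSP, 3.76% for preTreg against mSP and 5.26% for Treg against preTreg. Of the false calls in Treg, preTreg, mSP and smSP, 36.3%, 14.7%, 45.7% and 35.9% lay in peaks with a mean under 10 there. Without such peaks the share of false calls was 9.79%, 5.29%, 14.5% and 10.3%, and 7.87% for mSP against smSP, so low peaks were part of the excess over 5% and the rest was not explained. With edgeR the share was 5.88%, 7.60%, 5.41% and 5.58% for genotype in the 4 populations. Such shares depend on the number of changed peaks, 200 here, so they do not give the share of false calls in the data. The limma test was kept since it was fixed in advance, with edgeR counts given beside it or in the section on processing. On draws without any change it made 0.1 false calls over all populations and 0.4 in the interaction test. Simulated libraries varied independently, with a spread set by the trend with signal and no difference between mice shared by their populations. The draws therefore do not show how many false calls such differences would give.

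Alternatives were another pseudocount, filter, scaling and tool, a fold threshold, the T8 libraries left out or assigned by description, each library left out, and blocks. Populations of a replicate share a mouse, so the cell type contrasts are paired by mouse, whereas sufficient and deficient mice share only a number. Deviations of libraries of 1 mouse correlated by -0.0092 to 0.0879 (median 0.0311) over 12 pairs, and no replicate pair differed by less than sampling noise (chi-square per degree of freedom 1.64 to 1.93). Calculations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.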

Results

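Chromatin accessibility was measured by ATAC-seq, which reads out where a transposase can insert into DNA, in 4 populations of CD4 single positive thymocytes sorted from mice with or without CNS4, a conserved non-coding sequence of the gene for the regulatory T cell factor Foxp3. The populations were Treg cells, sorted by a Foxp3-GFP reporter, preTreg cells, which carried CD25 (the IL-2 receptor alpha chain) without Foxp3-GFP, and CD25-negative cells labelled mature (mSP, low CD24) or semimature (smSP, high CD24). Each population came from 2 CNS4-sufficient and 2 CNS4-deficient mice, which gave 16 libraries in 8 groups of 2. The table held 73442 peaks, and each library had between 5585827 and 11437401 reads in them. The principal component analysis put the 4 populations apart, with 59.4% of the variance on the first component and 14.1% on the next. In all 4 mice the libraries labelled mSP and smSP differed at some maturation genes, Cd24a, Klf2, S1pr1 and Ccr7 among them, in a direction opposite to their sort markers, as described with the comparison of these populations, so both are named here by their labels only. For 1 CNS4-deficient mouse, T8, the descriptions of these 2 libraries also named the opposite populations from the titles, and the titles were followed.

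**Figure D1:**
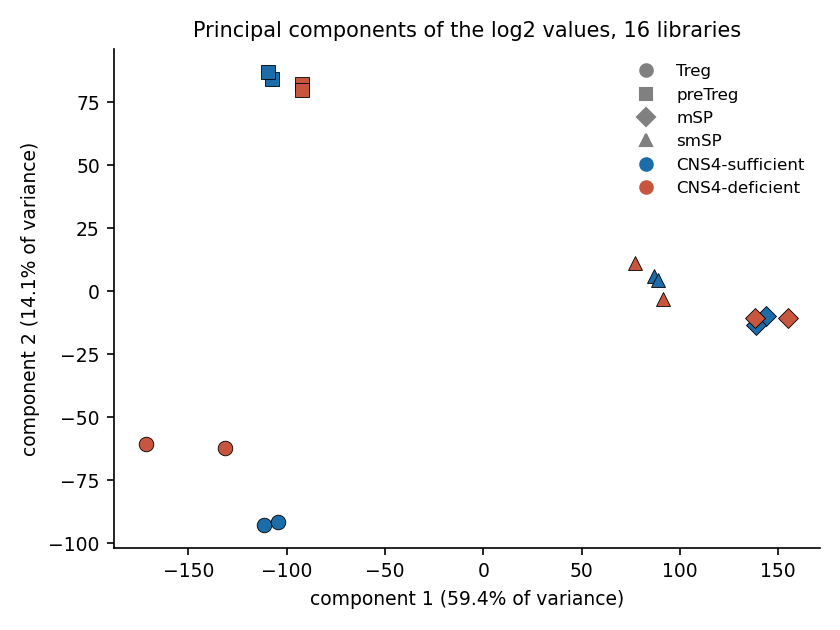
Principal components 1 (59.4% of the variance) and 2 (14.1%) of the log2 normalised read counts of the 16 libraries, 1 point per library, with shapes for the labelled populations and colours for genotype. The 4 libraries of each labelled population lie together, and those labelled smSP lie between those labelled mSP and the preTreg and Treg libraries on component 1.

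The deletion of CNS4 was read first from the Foxp3 locus, where 12 peaks were tested. The peak at X:7570739-7571052 (mm10), within the gene body of Ppp1r3f centred at -8.78 kb from the Foxp3 gene start, had 0 reads in all 8 libraries of CNS4-deficient mice. In CNS4-sufficient mice its normalised read count was 128 ± 16.2 in Treg, 50.0 ± 2.91 in preTreg, 51.2 ± 4.97 in libraries labelled mSP and 77.5 ± 13.6 in those labelled smSP (mean ± SD, n = 2 each). Against a floor of 3 reads over the 2 deficient libraries, the peak was at least 79.6-fold lower in Treg, 36.2-fold in preTreg, 26.7-fold in mSP and 43.0-fold in smSP. Adjusted p values by limma were 1.37e-08, 1.82e-06, 1.59e-06 and 2.61e-07 in that order. It was the 1 peak of the table with 0 reads in all 8 deficient libraries and a mean above 10 in the sufficient ones, and the genotype labels of all 16 libraries matched it. The other locus peaks were not called by limma between genotypes when adjusted over all peaks. Adjusted over the 12 locus peaks alone, 4 more passed by limma. The 12 include the deleted peak, whose low p value loosens the adjustment of the others. An adjustment without it would be stricter and was not run, so the call in preTreg may not hold. In Treg these were X:7572485-7572749 (87.2 ± 14.0 in sufficient and 138 ± 0.572 in deficient cells, n = 2 each, limma adjusted p = 0.0148) and X:7574006-7574160 (70.8 ± 10.1 and 42.6 ± 3.52, limma adjusted p = 0.0148). In preTreg it was X:7567524-7567768 (23.4 ± 5.65 and 9.66 ± 4.53, limma adjusted p = 0.0274), and in smSP X:7566433-7566684 (55.8 ± 12.1 and 29.1 ± 12, limma adjusted p = 0.00394). Over all peaks edgeR called the first in Treg (adjusted p = 0.0427). Within the Foxp3 gene body, the Treg peak at X:7583902-7584149 was 97.9 ± 19.7 in sufficient and 188 ± 26.0 in deficient Treg cells, and that at X:7584167-7584401 was 69.3 ± 3.54 and 146 ± 4.63 (n = 2 each). For these 2 peaks the adjusted p was 0.685 and 0.637 by limma and 0.0125 and 0.00545 by edgeR, so the call rested on the tool. At the other end of the gene lay the peaks at X:7595027-7595312 and X:7595380-7595548, assigned to Ccdc22. They were 94.6 ± 0.823 and 50.7 ± 7.34 in sufficient and 51.9 ± 10.9 and 27.3 ± 0.766 in deficient Treg cells. Neither tool called them (adjusted p = 0.716 and 0.767 by limma, 0.0703 and 0.156 by edgeR). At these peaks and the 2 within Foxp3, the limma fit took its spread from all 8 groups. Libraries outside Treg held between 0 and 4 reads there, so the limma result does not read the spread of the Treg libraries alone.

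**Figure D2:**
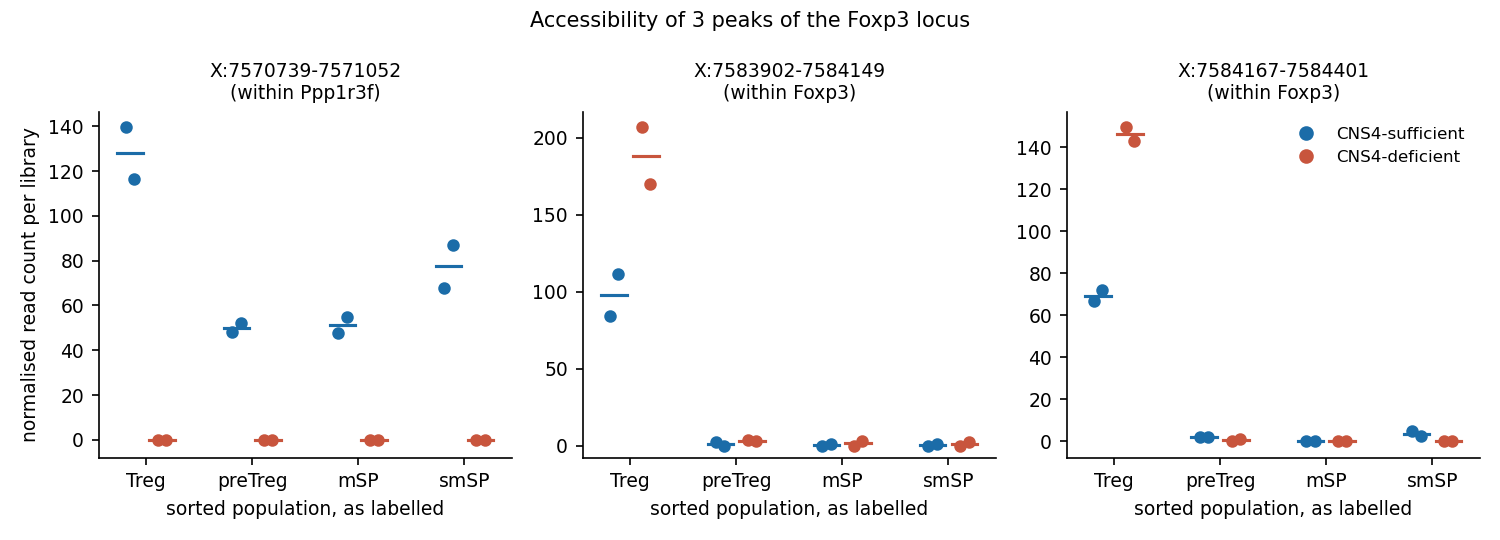
Normalised read counts per library at 3 peaks of the Foxp3 locus on chromosome X, by labelled population (horizontal axis) and genotype (colour); points are libraries and lines are means of 2. The peak upstream of Foxp3 is at 0 in all 8 CNS4-deficient libraries, and both peaks within Foxp3 are open in Treg libraries.

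Libraries labelled mSP and smSP were compared to read the change from semimature to mature cells. Cd24a, the gene of the sort marker that was low in mSP cells, was more open in the libraries labelled mSP, with 8 of 9 peaks higher, 0 lower and a median log2 fold of 0.95. Rag1, which recombines antigen receptor genes in immature thymocytes, had 1 peak, higher by 0.79. Genes of mature cells that leave the thymus were less open in these libraries. S1pr1, the egress receptor, had 26 of 34 peaks lower and 1 higher, Klf2, which drives S1pr1, had 9 of 14 lower, and the chemokine receptor gene Ccr7 had 15 of 28 lower and 1 higher. The medians of Cd24a were 0.85, 0.73, 0.95 and 0.93 in mice T9, T10, T7 and T8, and those of S1pr1 were -0.97, -1.19, -1.01 and -0.50. Not all genes moved this way: Cd69, an early activation marker of immature single positive cells, had 8 of 32 peaks lower and 0 higher in the libraries labelled mSP, Satb1 had 7 of 74 higher and 8 lower, and Cd44 of the mature list had 5 of 26 higher and 1 lower. These genes were singled out after their values were seen, and a direction given for mSP or smSP is that of the labels.

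**Figure D3:**
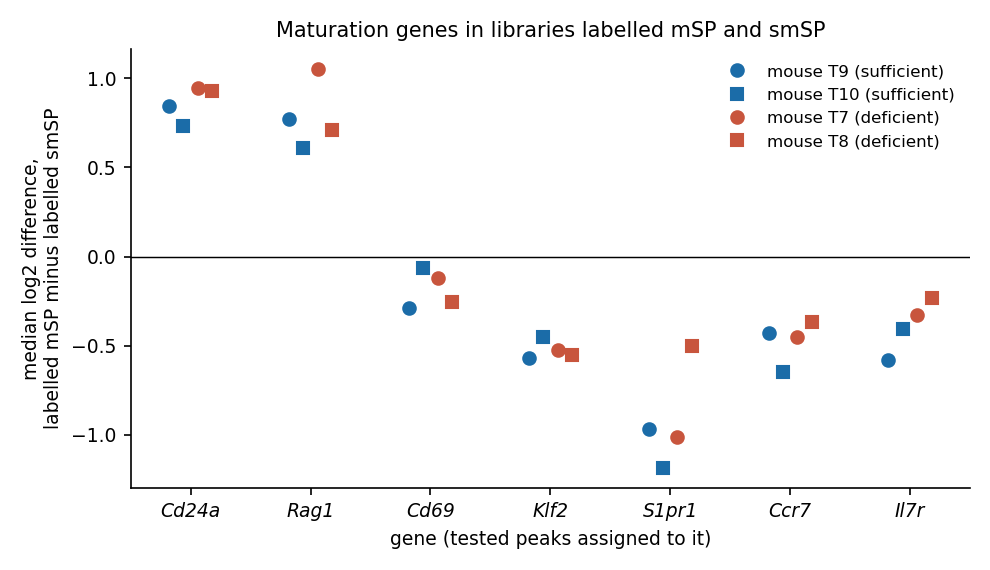
Median log2 difference (vertical axis), libraries labelled mSP minus those labelled smSP, over the tested peaks of 7 maturation genes, 1 point per mouse with colours for genotype. Cd24a lies between 0.73 and 0.95 and S1pr1 between -1.19 and -0.50 in the 4 mice.

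Across all peaks, 11664 of 73140 differed between the libraries labelled mSP and smSP by limma, 6328 higher and 5336 lower in mSP. The larger direction turned with scaling, with 5439 higher and 6413 lower at equal library totals and 5387 and 6181 after quantile normalization, so it is not read here. Among the largest folds, a peak in Tns3 was 67.8 ± 18.7 in mSP and 6.64 ± 4.12 in smSP, and a peak in Arid5b was 8.15 ± 6.02 and 43.3 ± 13.4 (n = 4 each). The list of mature thymocyte and egress genes was lower as a set, with 84 peaks lower and 10 higher of 260 (adjusted over the list alone, 103 and 17), a median log2 fold of -0.28 and a camera adjusted p of 1e-10 (0.0121 with an estimated correlation). TCR and co-stimulation response genes were lower too, with 95 lower and 16 higher of 448 (adjusted over the list alone, 107 and 20), as were NF-kB pathway genes, with 24 lower and 10 higher of 155 (30 and 13), and Treg signature genes, with 68 lower and 21 higher of 346 (85 and 31). Their camera adjusted p values were 1.01e-06, 0.000302 and 0.000257, and 0.000259, 0.0162 and 0.0166 as adjusted p with an estimated correlation. IL-2 and STAT5 targets had 27 lower and 9 higher of 159 (30 and 9), with a camera adjusted p of 0.00815 that became an adjusted p of 0.0615 with an estimated correlation. The immature thymocyte list was mixed, with 26 higher and 22 lower of 231 (29 and 23; camera adjusted p = 0.839). A Sox4 peak was 68.9 ± 10.1 in mSP and 11.7 ± 5.50 in smSP, whereas a Satb1 peak was 35.6 ± 6.33 and 104 ± 8.55 (n = 4 each). The lists for CD4 lineage commitment, recirculating or effector Treg cells, innate-like, B, myeloid, and erythroid and stromal cells were not called, with camera adjusted p values of 0.609, 0.839, 0.906, 0.36, 0.609 and 0.827. By the titles edgeR called 12611 peaks and DESeq2 7446. On simulated data with 200 changed peaks 12.9% of the limma calls were false, a share that does not carry over to 11664 calls. With the T8 libraries assigned by description, limma called 0 peaks (8446 at an unadjusted p under 0.05), edgeR 0 and DESeq2 12.

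The comparison of preTreg cells with the libraries labelled mSP covered the precursor stage, and 42645 peaks differed by limma, 21132 higher and 21513 lower in preTreg. The split was 22186 and 20088 after quantile normalization, and 6211 and 10416 at an absolute log2 fold of at least 1. By edgeR 42811 peaks differed, 19917 higher and 22894 lower. Treg signature genes were more open as a set in preTreg, with 175 peaks higher and 69 lower of 346 (adjusted over the list alone, 177 and 69) and a median log2 fold of 0.46. A peak 44239 bp outside Nrp1, a surface receptor of thymic Treg cells, was 430 ± 50.2 in preTreg and 2.18 ± 1.69 in mSP, and a peak in Nt5e, which encodes the ectoenzyme CD73, was 143 ± 23.4 and 3.88 ± 3.69 (n = 4 each). NF-kB pathway peaks were higher in 89 and lower in 16 of 155 cases (89 and 16), TCR and co-stimulation response peaks in 180 and 99 of 448 (180 and 99), IL-2 and STAT5 target peaks in 73 and 25 of 159 (74 and 25), and recirculating or effector Treg peaks in 56 and 27 of 104 (57 and 27). Peaks in Il2rb, an IL-2 receptor chain, were 424 ± 64.7 against 25.0 ± 5.36, and in Nfatc1, a TCR-activated factor, 277 ± 15.5 against 12.7 ± 5.16. Camera adjusted p values of these 5 lists, in the order given, were 1.12e-05, 3.24e-06, 0.0337, 0.000889 and 0.000762, and each was below 0.05 with an estimated correlation as well. The immature thymocyte list was lower, with 161 peaks lower and 19 higher of 231 (162 and 19), a median of -0.96 and a camera adjusted p of 4.58e-12. The B cell list, with 4 of 7 peaks lower (5 over the list alone), had a camera adjusted p of 0.0131, and erythroid and stromal genes, with 7 lower and 2 higher of 12, had 0.0484, which became an adjusted p of 0.132 with an estimated correlation. The mature thymocyte and egress, CD4 lineage commitment, innate-like and myeloid lists were not called (camera adjusted p = 0.168, 0.521, 0.434 and 0.297). With the libraries labelled smSP in place of mSP, 34586 peaks differed, of which 30044 were called in both comparisons and 29915 in the same direction. In that comparison the mature thymocyte and egress list had a median of -0.18 in place of 0.11, and the TCR list a median of 0.05, neither called by camera (adjusted p = 0.0643 and 0.863). There the camera adjusted p of 0.0104, 0.0161 and 0.0269 for IL-2 and STAT5 targets, B cells, and erythroid and stromal cells became adjusted p values of 0.0572, 0.0572 and 0.103 with an estimated correlation.

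Treg cells were set against preTreg cells to read what accompanies Foxp3 expression. By limma 21051 peaks differed, 10369 higher and 10682 lower in Treg, or 11540 and 8937 at equal library totals. By edgeR 22226 differed, 11864 higher and 10362 lower. The Foxp3 peak at X:7584167-7584401 was 108 ± 44.6 in Treg and 1.1 ± 0.829 in preTreg, and that at X:7595027-7595312, where the gene bodies of Foxp3 and Ccdc22 overlap, was 73.3 ± 25.5 and 1.55 ± 0.808 (n = 4 each). In all, 7 of the 12 locus peaks were higher in Treg. The peak of the CNS4 region was not called (log2 fold 0.67, limma adjusted p = 0.264), but this comparison averages both genotypes and its deficient libraries were at 0. In sufficient mice alone that peak was 128 ± 16.2 in Treg and 50.0 ± 2.91 in preTreg (n = 2 each). Treg signature genes were more open, with 127 peaks higher and 34 lower of 346 (adjusted over the list alone, 137 and 36; median log2 fold 0.29), including Ikzf4, a transcription factor gene, at 59.3 ± 28.2 against 5.97 ± 6.51. A peak 16550 bp outside Il2ra, the CD25 gene, was 103 ± 5.47 in Treg and 9.26 ± 3.68 in preTreg. The immature thymocyte list was higher in Treg, with 79 higher and 10 lower of 231 (85 and 12), a median of 0.28. Most of this rise was in the sufficient mice: the list mean on the log2 scale was 5.70 and 5.74 in their Treg and 5.18 and 5.17 in their preTreg libraries, against 5.21 and 5.43 and 5.19 and 5.23 in the deficient mice. Camera adjusted p was 4.56e-07 for both lists, 0.0106 and 0.0452 as adjusted p with an estimated correlation. The TCR and co-stimulation response list, with 115 higher and 49 lower of 448 (119 and 53), and the B cell list, with 4 higher and 0 lower of 7 (4 and 0), were called with either correlation (camera adjusted p = 0.0199 and 0.00363). NF-kB pathway genes (33 higher, 9 lower of 155; 33 and 9 over the list alone) and mature thymocyte and egress genes (76 and 40 of 260; 79 and 44) had camera adjusted p values of 0.0300 and 0.0199 that became adjusted p values of 0.0901 and 0.207 with an estimated correlation. With 1 peak per gene the direction of the TCR and NF-kB lists turned, and neither was called (adjusted p = 0.147 and 0.291). A TCR list peak in Nfatc1 was 31.2 ± 15.5 in Treg and 277 ± 15.5 in preTreg. Single peaks near genes of effector and innate-like T cells were lower: Tbx21, the T-bet gene, was 5.43 ± 2.24 against 57.7 ± 8.51, Nkg7 was 28.8 ± 7.89 against 127 ± 15.8, and Cxcr3 was 17.0 ± 5.26 against 102 ± 19.1. Other peaks of these lists were higher, such as 1 in Rora (log2 fold 2.36) and 1 assigned to Eomes (1.44). As sets, the innate-like list (12 lower, 5 higher of 38), the recirculating or effector Treg list (27 lower, 21 higher of 104), IL-2 and STAT5 targets (35 higher, 20 lower of 159) and the CD4 lineage, myeloid, and erythroid and stromal lists were not called (camera adjusted p = 0.0837, 0.362, 0.132, 0.957, 0.187 and 0.0648).

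Loss of CNS4 was then compared within each population. In Treg cells 1294 peaks differed by limma, 507 higher and 787 lower in CNS4-deficient mice. The immature thymocyte list stood out, with 17 peaks lower and 0 higher of 231 (adjusted over the list alone, 55 and 1), a median log2 fold of -0.39 and a camera adjusted p of 1.2e-16 (0.0141 with an estimated correlation). Of the 17 peaks, 9 were assigned to Arpp21, 4 to Satb1, 2 to Sox4 and 1 each to Ccr9 and Cd8b1. These counts rested on single libraries, since 4, 2, 2 and 39 list peaks were called lower without Treg_FL 1, Treg_FL 2, Treg_KO 1 or Treg_KO 2, and 0 higher in each case. With 1 Treg library left out the list median stayed negative, from -0.25 (without Treg_KO 1) to -0.48 (without Treg_KO 2). Arpp21, which is expressed in double positive thymocytes, had log2 folds from -1.87 to -0.77, and Satb1, a chromatin organiser of thymocytes, from -1.48 to -0.76. The Treg signature list (3 higher, 3 lower of 346; 6 and 4 over the list alone) and IL-2 and STAT5 targets (1 higher, 0 lower of 159; 0 and 0) had medians of 0.09 and 0.11 and a camera adjusted p of 0.0446 each, and an adjusted p of 0.109 each with an estimated correlation. The erythroid and stromal list, of 12 peaks, had a median of -0.22 and an adjusted p of 0.0447, and 0.117 as an adjusted p with an estimated correlation. Called members of the Treg signature list included peaks of Tigit (log2 fold 0.49) and Tnfrsf18 (0.75), which were higher, and of Nrp1 (-0.53) and Ikzf2 (-0.69), which were lower. Among the largest folds outside the Foxp3 locus, a peak in Gsdme went from 15 ± 4.58 to 0 reads in both deficient libraries and a peak in Marchf3 was 16.2 ± 1.47 in sufficient and 75.0 ± 24.6 in deficient cells (n = 2 each). On simulated data with 200 changed peaks 14.6% of the limma calls of this comparison were false. The edgeR test called 2032 peaks, 1150 higher and 882 lower, and DESeq2 585, 321 higher and 264 lower, so the larger direction depended on the tool. Without Treg_FL 1, Treg_FL 2, Treg_KO 1 or Treg_KO 2, limma called 243, 422, 176 and 2919 peaks (253 higher and 169 lower without Treg_FL 2), and with the T8 populations from the description 260. At an absolute log2 fold of at least 1, 203 were higher and 394 lower.

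**Figure D4:**
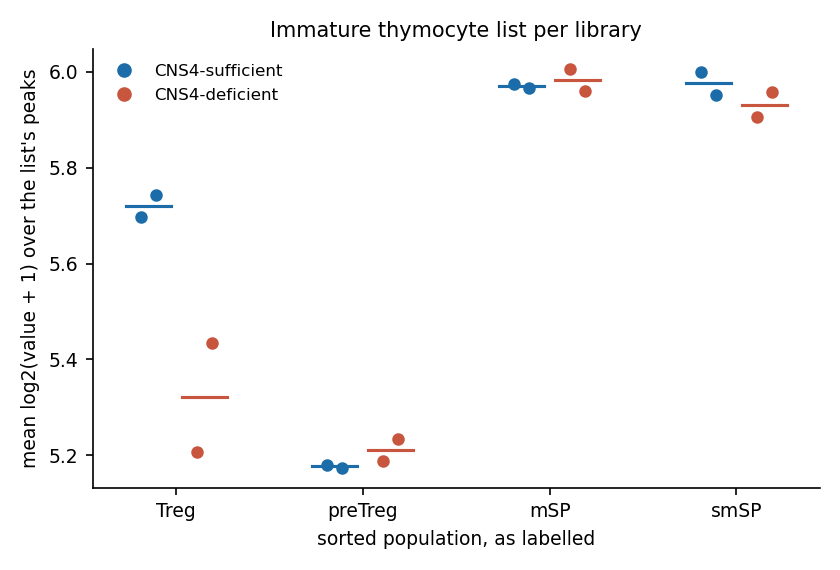
Mean log2(value + 1) over the 231 peaks of the immature thymocyte list (vertical axis) in each library, by labelled population and genotype; lines are means of 2 libraries. CNS4-sufficient Treg libraries lie at 5.70 and 5.74 and deficient ones at 5.21 and 5.43, and preTreg libraries of both genotypes lie between 5.17 and 5.23.

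In preTreg cells 299 peaks differed by genotype, 261 higher and 38 lower in deficient mice. Apart from the CNS4 region, the lower peaks with the largest folds were near heat shock genes and on chromosome 1. Hspa1a, which encodes an inducible HSP70 chaperone, was 47.6 ± 22.5 in sufficient and 3.22 ± 3.25 in deficient cells, and Hspa1b 41.4 ± 8.87 and 5.06 ± 3.24 (n = 2 each). A peak in Serpinb10 (1:107533818-107534102) was 135 ± 18.2 and 6.45 ± 1.32. Among higher peaks, that nearest Tgfbr2, a TGF-beta receptor gene, was 31.0 ± 9.88 in sufficient and 75.6 ± 14.6 in deficient cells. The mature thymocyte and egress list had 4 peaks higher and 0 lower of 260 (adjusted over the list alone, 6 and 1), in Ccr7, Il6ra and S1pr1, and a camera adjusted p of 0.0228 that became an adjusted p of 0.235 with an estimated correlation. No other list was called by camera, the lowest adjusted p of the others being 0.0984. On simulated data 6.10% of the limma calls were false, and edgeR called 692 peaks, 551 higher and 141 lower. Without preTreg_FL 1, preTreg_FL 2, preTreg_KO 1 or preTreg_KO 2, limma called 91, 32, 7 and 176 peaks (1 higher and 6 lower without preTreg_KO 1), and with the T8 populations from the description 9. At an absolute log2 fold of at least 1, 25 were higher and 25 lower.

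In the libraries labelled mSP 180 peaks differed by genotype, 119 higher and 61 lower in deficient mice, and in those labelled smSP 62, 27 higher and 35 lower. The CNS4 region, Serpinb10 and Hspa1a or Hspa1b again had the largest folds among lower peaks. Serpinb10 was 151 ± 26.5 in sufficient and 2.58 ± 0.407 in deficient mSP libraries, and 128 ± 8.60 and 2.72 ± 3.84 in smSP libraries (n = 2 each). A peak in Rora, a nuclear receptor gene, was 1.57 ± 2.22 and 11.2 ± 5.07 in smSP, higher in deficient mice. In mSP libraries camera called the mature thymocyte and egress, Treg signature, and IL-2 and STAT5 lists (adjusted p = 0.00313, 0.0188 and 0.0188), with medians of 0.13, 0.08 and 0.11 and 0, 1 and 0 peaks higher and 0, 0 and 1 lower, and the adjusted p was 0.129 for each with an estimated correlation. In smSP libraries no list was called, the lowest camera adjusted p being 0.0529. Of the limma calls on simulated data 25.1% were false in mSP and 15.4% in smSP, and edgeR called 301 and 79 peaks, 243 and 41 of them higher, and DESeq2 234 and 63, 206 and 34 of them higher. With the T8 populations from the description the counts were 13 and 17, and without the T8 libraries 468 and 450. The larger direction in mSP was not stable: 209 peaks were higher and 259 lower without the T8 libraries, 41 and 115 without mSP_KO 1, 178 and 196 without mSP_KO 2, and 29 and 40 at an absolute log2 fold of at least 1. In smSP it was not stable either, with 18 higher and 8 lower without smSP_FL 1 and 53 and 28 without smSP_FL 2. Without mSP_FL 2 or mSP_KO 2, 28 and 374 peaks were called in mSP. In smSP the count was 26, 28 and 260 without smSP_FL 1, smSP_KO 1 or smSP_KO 2, and 36, 34, 37 and 39 without Treg_FL 1, Treg_FL 2, preTreg_FL 1 or preTreg_FL 2. It was 100 and 99 without mSP_KO 1 or mSP_KO 2.

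Averaged over the 4 populations of each mouse, 1727 peaks differed by genotype by limma, 1260 higher and 467 lower in the 2 deficient mice, most by small folds. At an absolute log2 fold of at least 1 there were 44, 12 higher and 32 lower. The Serpinb10 peak fell by 4.65 on the log2 scale, the intergenic peak at 1:108040935-108041207 by 3.54 and the Hspa1a peak by 3.04 (adjusted p = 2.49e-14, 2.07e-12 and 9.04e-05, limma, n = 2 mice per genotype). Such low p values lean on the spread of other peaks, not on that between the 2 mice of a genotype alone. With the mouse as a random block over 16 libraries 2908 peaks were called, and without FL mouse 2 or KO mouse 2 the count was 521 and 5023. The random block used a within-mouse correlation of -0.0075, so it treats the 16 libraries almost as independent, and its count does not take the mouse as the replicate. Library numbers in the descriptions run by mouse, with the deficient mice first, and no label gives a batch or day of processing.

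The effect of genotype differed between populations at 294 peaks by the limma F test, at 472 with the mouse as a block, and at 1 with the T8 populations from the description. For the immature thymocyte list the genotype difference in Treg was below that in preTreg by 0.39 on the log2 scale (camera adjusted p = 1.40e-10, and 0.0793 as adjusted p with an estimated correlation). Without Treg_FL 1, Treg_FL 2, Treg_KO 1 or Treg_KO 2 the count was 33, 36, 48 and 1101. It was 191, 194, 147 and 184 without preTreg_FL 1, preTreg_FL 2, preTreg_KO 1 or preTreg_KO 2, and 132 without mSP_FL 2.

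The place of preTreg cells between the libraries labelled mSP (0) and Treg cells (1) was measured in each mouse on peaks chosen in mice of the other genotype. It was 0.906 and 0.942 in the 2 sufficient mice and 0.654 and 0.741 in the 2 deficient mice, a difference of -0.23. The exact permutation test gave p = 0.333, which is the smallest value that 2 mice against 2 can give, so the test could not pass 0.05. The end of the scale moved as well, since Treg cells differed by genotype at 1294 peaks, and the peaks differed between genotypes by construction. With smSP as the start the difference was -0.24.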

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

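The tests of sorting, effector cells, heat shock and handling and the T8 label test were chosen after the related result was seen; the thinning test, the test of later thymocyte genes and the splits were not.

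At some genes the labels of the mSP and smSP libraries run against their sort markers, with Cd24a more open and S1pr1, Klf2 and Ccr7 less open in the libraries labelled mSP of all 4 mice. A candidate explanation is that the mSP and smSP labels were exchanged in all 4 mice; later thymocyte genes outside the fixed lists, written down before their values were seen, had a median log2 fold of -0.25 (16 of 67 peaks lower, 2 higher), negative in each mouse, while double positive genes had 0.08 (9 higher, 4 lower of 70), below a bound of 0.1 that had been considered for them and not set. Most of the lower peaks of later thymocyte genes were in 1 gene family, Gimap3 to Gimap7 (3, 2, 2, 2 and 1), and in Cd55 (4). Slfn1 and Slfn2 had 0 called, and Emb had 1 lower and 2 higher. The TCR response, NF-kB, Treg signature and IL-2 lists also had negative medians (-0.18, -0.17, -0.16 and -0.12). Those of the recirculating or effector Treg, B cell, and erythroid and stromal lists were above 0 (0.02, 0.28 and 0.03). A negative median was thus not particular to maturation genes, and that of the later thymocyte genes does not decide on an exchange. An exchange in T8 alone, as its descriptions would have it, is argued against by the T8 library labelled mSP. That library lay at 0.905 on the scale from smSP (0) to mSP (1) built from the other mice. The lower TCR response list and Cd69 in the libraries labelled mSP go with the labels as given, so the exchange is a hypothesis, no library was reassigned, and no biological explanation was tested. If it held, every direction between these populations would turn around, and preTreg would have been compared with the semimature cells.

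The effect of genotype differed between populations at 294 peaks by a test of the difference itself. The immature thymocyte list differed between Treg and the other populations by -0.39 against preTreg, -0.39 against mSP and -0.35 against smSP (camera adjusted p = 1.40e-10, 1.40e-10 and 5.15e-08, and adjusted p = 0.0793, 0.0793 and 0.118 with an estimated correlation), and the mature thymocyte and egress list by -0.17 against preTreg (camera adjusted p = 0.0391) and -0.18 against mSP (0.0147), with adjusted p values of 0.377 and 0.323 with an estimated correlation. Against smSP the latter list had -0.097 and was not called (0.176, and 0.474 with an estimated correlation).

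For the lower immature thymocyte list in deficient Treg cells, thinning all Treg libraries to 6580710 reads left a median log2 fold of -0.37. Thinned counts were rescaled to equal totals, so thinning could remove only what unequal counting noise and the added 1 do to a fold. It argues against sequencing depth by that route alone. Single positive cells in the sort of sufficient Treg cells stay open for at least a part of the difference. Of 234 Treg-specific peaks, 28 were higher in deficient cells by edgeR, and the median log2 fold of the 234 was 0.19. Such cells could give this rise by dilution, but so could the genotype. Dilution alone would lower none of these peaks, and 2 were lower, too few to decide. Whether dilution of this size could give the whole list difference was not tested. A higher share of recirculating or effector Treg cells among deficient cells also stays open, with a median of 0.13 for that list, which was not called. The median was -0.40, -0.38, -0.25 and -0.48 without Treg_FL 1, Treg_FL 2, Treg_KO 1 or Treg_KO 2, and the adjusted p with an estimated correlation 0.0289, 0.0508, 0.00173 and 0.000286. An effect of CNS4 on the Treg population is the biological explanation the design gives, and it was not tested apart from other differences between the mice.

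Peaks within the bodies of 13 heat shock genes had median log2 folds of -0.28, -0.39, -0.31 and -0.37 in deficient Treg, preTreg, mSP and smSP cells, with 2, 8, 3 and 3 of 49 called lower and 0 higher. Averaged over the populations 23 were called lower and 0 higher, and no set test was run on this list. Peaks outside the gene bodies are not counted, among them that near Hspa1a at 17:34968298-34968871 (246 in sufficient and 23.5 in deficient preTreg, 216 and 12.8 in smSP) and the Hspa1b peak named for preTreg. An action through Foxp3 in Foxp3-expressing cells is argued against by the smSP libraries, where the median log2 fold was -0.37 (quartiles -0.71 and -0.15). Handling that differed between the mice of the 2 genotypes may also lower immediate early genes, whose median over all populations was -0.21 (7 of 47 called lower), but no label records handling, and with 2 mice per genotype it cannot be told apart from genotype.

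Other splits of the 8 libraries were counted with a fit of the 2 populations alone. Populations of a mouse are paired, so the real split is compared with the 8 splits that part all 4 mouse pairs, itself included. In each cell type comparison 1 of the 8, the real one, gave as many peaks, and 8 splits are too few for a share under 0.05. The real split gave 9517 peaks for mSP and smSP, 41071 for preTreg and mSP and 17511 for Treg and preTreg, and the highest of the other 7 gave 0 in each. The other 27 of the 35 splits keep both libraries of at least 1 mouse together, and they gave at most 7, 2 and 1 peaks.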

How the results depend on the processing

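The filter by compared cell types, cyclic loess, smSP in place of mSP, the Treg library tests of the immature list, and each mouse left out were chosen after the data were seen, and the others were planned. The cause of changes was not tested. By edgeR, counts were 2032 (genotype in Treg), 692 (preTreg), 301 (mSP) and 629 (interaction), and 7 Foxp3 locus calls; by DESeq2, 585 (Treg) and 7446 (mSP against smSP). With an absolute log2 fold of at least 1 they were 597, 50, 69 and 29 for genotype in Treg, preTreg, mSP and smSP, and 2399, 16627 and 6313 for the 3 cell type contrasts. With T8 populations from the description they were 260, 9, 13 and 17 for genotype, 1 for the interaction and 0 by limma for mSP against smSP (8446 at an unadjusted p under 0.05, 0 by edgeR and 12 by DESeq2); without the T8 mSP and smSP libraries, 468 (mSP), 450 (smSP) and 661 (interaction). FL or KO libraries alone gave 4012 and 5002 peaks for mSP against smSP, and KO alone 11004 for Treg against preTreg. The replicate block by number, which pairs nothing by design, gave 461 (preTreg), 327 (mSP) and 178 (smSP); the mouse block gave 472 for the interaction and changed no other cell type call beyond 1.5 times. Over all populations, counts were 2908 with the mouse as a random block, 2711 with no block and 1044 for Treg and preTreg only. Called lists were 27 of 84, 16 with an estimated correlation and 13 with 1 peak per gene. The axis difference was -0.17 at an absolute log2 fold of 2. Leaving out 1 library gave 176 to 2919 peaks (Treg), 7 to 433 (preTreg), 28 to 374 (mSP), 26 to 260 (smSP), 33 to 1101 (interaction), 521 to 5023 (over all populations, 1 mouse), 7781 to 12523 (mSP against smSP), 38580 to 43039 (preTreg against mSP), 17207 to 21539 (Treg against preTreg), 4 to 4 locus calls and an axis of -0.27 to -0.18; a lone library is then assumed to vary like other groups. Reversed were Ppp1r3f peak_82300 (-0.15) and Zbtb46 peak_49998 (0.12) for mSP against smSP with T8 from the description, Vangl2 peak_4962 (-0.083) for Treg and preTreg only, and the TCR (adjusted p = 0.147) and NF-kB (0.291) lists for Treg against preTreg with 1 peak per gene. Of 235 named peaks, 155 kept direction and call under the alternatives run for each, filters, DESeq2 and subsets not covering all. Lists were run only with an estimated correlation, 1 peak per gene, quantile normalization and, for cell types, the replicate block, and 63 of 84 list results kept direction and call under these.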

Other observations

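A pair of sites on chromosome 1 had lower means in deficient mice in all 4 populations and lies far from Foxp3. The peak in Serpinb10 (1:107533818-107534102) was 41.3, 135, 151 and 128 in sufficient Treg, preTreg, mSP and smSP cells and 3.26, 6.45, 2.58 and 2.72 in deficient ones (means of 2 libraries). The peak at 1:108040935-108041207 was 23.4, 151, 100 and 65.5 in sufficient and 8.35, 3.22, 6.74 and 5.12 in deficient cells, less than 4-fold lower in Treg. By the ratio of means with 1 added to each, 3 peaks were at least 4-fold lower in deficient cells of all 4 populations. They lay in Serpinb10, near Hspa1a and at the CNS4 region. The added 1 left out weaker peaks, such as that at 17:34969217-34969364 in Hspa1a (8.90 in sufficient and 1.57 in deficient Treg). The pair was singled out after its values were seen. Tests of explanations of the pair, made at an earlier stage, were dropped, and no explanation is weighed here.

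Positions of the single positive libraries on the scale from libraries labelled smSP (0) to those labelled mSP (1), set in the other 3 mice, were 0.942, 0.931, 0.950 and 0.905 for those labelled mSP and 0.0865, 0.0870, -0.0658 and 0.260 for those labelled smSP, in mice T9, T10, T7 and T8.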
